A study of Mus musculus with 4 samples.

How the data were processed

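RNA was measured in 4 cultures of mouse Th17 cells, 2 transduced with a retroviral vector carrying a guide against Adarb1 (sgAdarb1) and 2 with the empty vector. The cells carried a Cas9 transgene, per the labels. Per the labels' protocols, naive CD4 T cells of mice aged 8 to 12 weeks were activated for 24 h with 0.25 µg/mL anti-CD3 and 1 µg/mL anti-CD28, transduced, and polarized for 72 h with 0.3 ng/mL TGF-β and 20 ng/mL IL-6. The cultures came from 2 donor mice, each of which gave a knockdown and a control culture, per the series' design text. Ribosome-depleted RNA was made into libraries with a KAPA kit and 8 PCR cycles, and these were sequenced on a NovaSeq, per the labels' protocols. Groups are named here from the sample titles, but no step assigned libraries to groups, and the fold changes rest on the authors' own grouping. The treatment tag contradicts the title for 2 of the 4 samples, since it gives both cultures of the first replicate as control and both of the second as knockdown. The titles go with the design text, in which each donor contributed both arms.

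The deposited table held 55450 genes with versioned identifiers, all of which matched GENCODE mouse release M21 on mm10, the source of the gene symbols, types and positions used here. The submitters' processing notes name STAR 2.6.1a, featureCounts and DESeq2 1.18.1 with the mm10 build. The formula of the authors' model, any donor term in it, the strand setting of the counting and the annotation are not given in the sources used here. For each gene the authors deposited, per the file headers, a mean signal, which is the mean over libraries of counts divided by DESeq2 size factors and is called the mean normalized count below. The authors also deposited a log2 fold change with its standard error. The Wald score, here called the Wald statistic, was deposited by the authors as well, and it equalled the log2 fold change divided by its standard error. The p-value deposited by the authors was the two-sided normal p of that statistic, and the deposited adjusted p equalled a Benjamini-Hochberg adjustment over all 29383 genes with a fold change. The other 26067 genes had a mean normalized count of 0.

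The table also held 4 columns of values per library whose names match none of the sample labels. They were not used in any step. Values per culture, library depths, refits, pairing by donor and omission of a library were therefore not computed, and every gene value is the authors'. The analysis planned for a table holding only the authors' comparison was used: no test of single genes beyond the deposited one, with a deposited adjusted p below 0.05 as the threshold. The table does not name the numerator of its fold changes. The design text sets the knockdown against the empty vector, and the sign is read in that order, with positive values as higher in sgAdarb1. If the authors used the opposite order, every sign turns. Their grouping of the libraries could not be checked either. Had it followed the treatment tag, the fold changes would set the second replicate against the first, not guide against vector.

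The genes, lists, threshold and first set of alternative settings were chosen before the data were examined. Named genes were Adarb1, Adar and Adarb2, the lineage genes Il17a, Il17f, Il22, Il21, Foxp3, Ifng, Gata3, Tbx21 and 1 more that is not reported here, and the 10 largest increases and 10 largest decreases past the threshold with a mean of at least 50. Up to 4 members past the threshold were to be named per list. If fewer than 10 genes passed, the 10 of smallest unadjusted p were to be named instead, as genes that did not pass. Predicted genes, pseudogenes and genes without a symbol were not named, and the minimum mean was not applied to this replacement. The 25 lists covered the Th17, Th1, Th2 and Treg programmes, naive and memory T cells, T cell activation, type I interferon response, RNA editing enzymes, ADAR2 editing substrates, p53 targets, cell cycle, glycolysis and hypoxia, and cholesterol synthesis. They also covered the integrated stress and unfolded protein responses, heat shock and immediate early genes, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, nuclear long non-coding RNAs, reference genes and sex-linked genes, with markers of B cells, CD8 T and NK cells, myeloid and dendritic cells, and erythroid cells. There were 2 genes that each stood in 2 lists, and Norad was not matched by symbol.

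Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistic, with a preset inter-gene correlation of 0.01, over the 14547 genes with a mean of at least 10. A list needed 5 tested members. The 23 lists that had them were adjusted together by Benjamini-Hochberg. The median log2 fold change of each list was set against 10000 random lists of the same size matched on mean expression. The correlation between genes was not estimated and fry was not run, since both need values per library. List p-values and percentiles take genes as the units and leave out differences between cultures that genes of a list share.

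The alternative settings fixed in advance that could be run were other adjusted p thresholds of 0.01 and 0.1, an added minimum absolute log2 fold change of 1, Benjamini-Hochberg adjustment over genes with a mean of at least 10 or 50, other filters for the list test, and cameraPR on ranks or on log2 fold changes. Added after the values were seen were a removal of the trend of fold change on GC content and transcript length (natural splines with 4 degrees of freedom each, weighted by the inverse squared standard error), Wald statistics divided by their robust SD in 20 bins of mean expression, protein-coding genes alone as the background of the list test, the Th17 list without Il17a and Il17f, and a preset correlation of 0.1. GC content and length came from the longest annotated transcript of each gene. Standard errors were compared with their running median over 501 genes ordered by mean expression.

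The steps were tested on simulated data built from the deposited means and standard errors of this comparison. In each of 20 simulations 200 of the 29383 genes were changed, all drawn from genes with a mean of at least 50. The threshold recovered 29.9% of genes changed by 0.5 on the log2 scale, 69.6% at 1, 94.5% at 2 and 99.7% at 3. With 200 genes changed together the adjusted threshold was easier to pass than for a gene passing alone. These rates therefore overstate recovery where few genes differ. Of the calls, 5.27% were false. In these gene simulations the noise was as wide as the deposited standard errors state. The observed Wald statistics were narrower, with an SD of 0.509 over all tested genes. In the list simulations the noise was set narrower than the deposited standard errors, near the observed Wald statistic SD of 0.585 among the genes tested. Over the 14547 genes of the list test and 50 simulations, 0.174% of list tests were called with no effect. A cell cycle list with each member lowered by 0.5 of its standard error was called in 88% of runs. Noise was drawn independently for each gene in all simulations, so these rates do not cover lists of correlated genes. With a simulated GC trend, 19.0% of list tests were called without correction and 0.174% with it. That trend was linear in GC content, steeper than the observed one, and removed by a fit on GC content itself. Its removal was therefore built in and does not test the correction on the deposited values. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.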

Results

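The transcriptomes of mouse Th17 cells, the IL-17-producing class of CD4 helper T cells, were measured by RNA sequencing after a CRISPR guide against Adarb1 was delivered to Cas9-expressing cells. Adarb1 encodes ADAR2, an enzyme that edits adenosine to inosine in double-stranded RNA. There were 2 cultures per group, from 2 donor mice, and the control was an empty vector without a guide. The authors' deposited table gives 1 fold change per gene between the groups, with its standard error (SE). Of the summed mean normalized counts in the authors' deposited table, the predicted gene Gm26917 took 9.55% (at 0.19 ± 0.07 on the log2 scale), Actb 1.14% and the mitochondrial ribosomal RNA mt-Rnr2 0.902%. Depths of single libraries were not used here. Fold changes are written as sgAdarb1 relative to empty vector, the order of the design text, since the table does not name its numerator. The grouping behind them is the authors' and could not be checked here.

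The comparison asked which transcripts differ between Th17 cells given the Adarb1 guide and cells of the same donors given the empty vector. No single gene passed the threshold: 0 of 29383 genes had an adjusted p below 0.05 in the authors' deposited table (DESeq2), and 61 had an unadjusted p below 0.05, 29 positive and 32 negative, where chance alone would give about 1469. Nearest to the threshold were Il17a, the signature cytokine of Th17 cells, on the positive side at 0.70 ± 0.15 (log2, SE), and Snord17, a small nucleolar RNA, on the negative side at -1.10 ± 0.24 in the authors' deposited table. Cpa3, a protease of mast cells, lay at -5.66 ± 1.26 in the authors' deposited table. As groups, cell cycle genes, mitochondrially encoded mRNAs, nuclear long non-coding RNAs and Th2 genes lay on the negative side, with small medians. Cholesterol synthesis, p53 target and Treg genes lay on the positive side, as did Th17 genes through Il17a and Il17f. Ribosomal protein, histone and glycolysis genes were also called on the positive side. These last calls ended when a trend of fold change on GC content and length was removed. Of the 11 list calls, 4 held at a higher preset correlation between genes, and none held when log2 fold changes replaced the Wald statistics.

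Adarb1 mRNA itself did not pass the test. The gene spans chromosome 10, 77290726 to 77418270 (mm10), on the minus strand. Its log2 fold change was 0.11 ± 0.12 at a mean of 2130 normalized counts in the authors' deposited table, with a 95% interval from -0.13 to 0.35 and an unadjusted p of 0.381. That interval excludes a log2 difference of 1 in either direction. A Cas9 cut can leave the amount of mRNA as it was, so this value neither checks the labels nor settles the sign. Adar, which encodes the related enzyme ADAR1 (chromosome 3, 89715022 to 89753446), lay at -0.03 ± 0.11 with a mean of 2637 in the authors' deposited table. Adarb2, a brain-enriched relative, had a mean of only 6.47 and a log2 fold change of -0.65 ± 1.75 in the authors' deposited table. Among RNA editing enzymes, 7 of 13 genes were tested, 3 positive and 4 negative (cameraPR adjusted p = 0.935). Known ADAR2 editing substrates, such as Flna at 0.10 ± 0.08 and Cyfip2 at 0.05 ± 0.08 in the authors' deposited table, were split 6 to 6 among 12 tested genes (adjusted p = 0.487). Editing levels were not analysed here.

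The 10 genes of smallest unadjusted p did not pass and are given as such. Il17a, Snord17 and Cpa3 shared an adjusted p of 0.0709 in the authors' deposited table, and the next value was 1.00. Il17a (chromosome 1, 20730905 to 20734496) had a mean of 1756 normalized counts and an estimated 1.63-fold difference, with an unadjusted p of 2.90e-06 in the authors' deposited table. Snord17 (chromosome 2, 144265979 to 144266216) lies within Snx5 on the same strand, and Snx5 had a mean of 5985 normalized counts in the authors' deposited table against 507 for Snord17, so reads of the host gene could enter its value. Cpa3 (chromosome 3, 20215620 to 20242181) had a mean of only 28.7 in the authors' deposited table, and its fitted fold change at that level is no bound. Ccl6, a chemokine of myeloid cells, was at 1.82 ± 0.63 with a mean of 72.0 in the authors' deposited table. Also positive were S100a6, a calcium-binding protein, and Lmna, which encodes lamin A and C, at 0.47 ± 0.18 and 0.32 ± 0.12 in the authors' deposited table. An annotated ribosomal RNA gene, CT010467.1, was at 0.43 ± 0.17 in the authors' deposited table from ribosome-depleted RNA. On the negative side, Tpr, a nuclear pore component, was at -0.30 ± 0.10, Smc4, a condensin subunit, at -0.30 ± 0.11, and Malat1, an abundant nuclear long non-coding RNA, at -0.21 ± 0.08 in the authors' deposited table. Tpr overlaps Odr4 on the opposite strand, at a mean of 601 in the authors' deposited table, and the strand setting of the counting is not given in the sources used here.

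**Figure D1:**
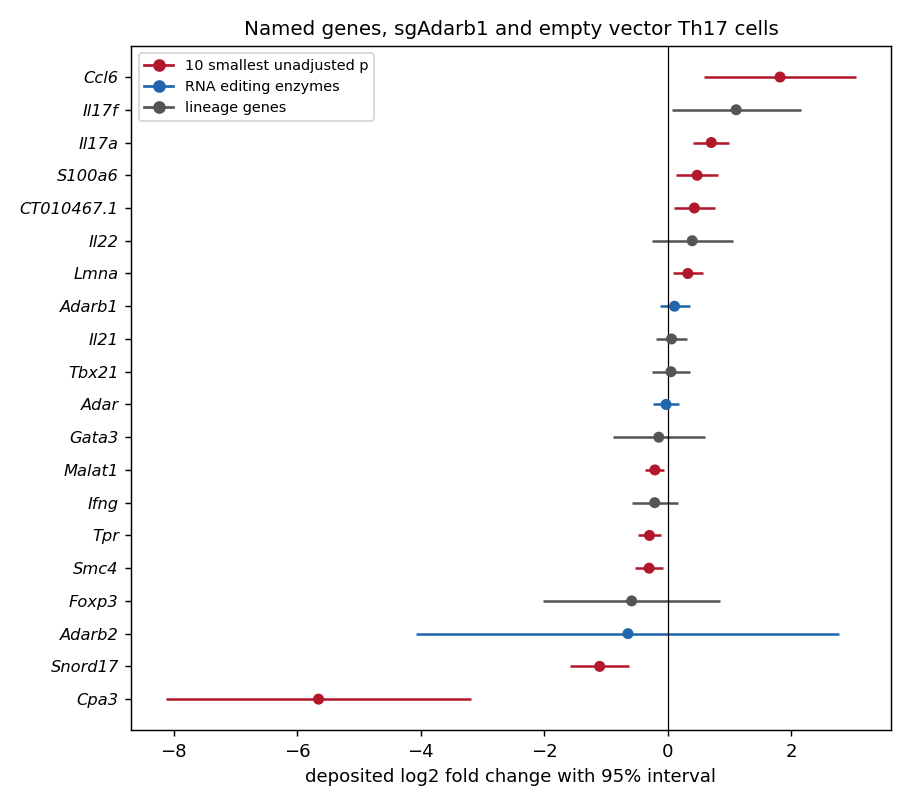
Log2 fold change (sgAdarb1 relative to empty vector, as read from the design text) of 20 named genes in the authors' deposited table, with horizontal bars for the 95% interval; red marks the 10 genes of smallest unadjusted p, blue the editing enzymes and grey the other lineage genes. Il17a lies at 0.70 and Snord17 at -1.10 with intervals away from 0, Adarb1 at 0.11 with an interval that spans 0, and no gene passed an adjusted p of 0.05.

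Th17 genes as a list lay on the positive side by their Wald statistics (33 tested, 21 positive and 12 negative, cameraPR adjusted p = 8.18e-04), while their median log2 fold change was 0.01, at percentile 58.7 of random lists. With the GC and length trend removed the median was 0.04, at percentile 98.4 (adjusted p = 5.04e-05). The uncorrected call rested on Il17a and Il17f: without them the adjusted p was 0.0882, and on ranks of the whole list 0.124. Adjusted over the list alone, 1 member passed (Il17a, adjusted p = 9.58e-05), against 0 over all genes tested. Il17f, the neighbouring cytokine gene (chromosome 1, 20777146 to 20790617), was at 1.11 ± 0.53 with an unadjusted p of 0.0383 in the authors' deposited table. Il22 was at 0.39 ± 0.34, with an interval that spans 0, and Il21 at 0.06 ± 0.13 in the authors' deposited table. Th2 genes lay on the negative side (9 of 11 tested, median -0.20, adjusted p = 0.0137), among them the cytokine genes Il4 at -0.27 ± 0.36, Il5 at -0.33 ± 0.53 and Il13 at -0.22 ± 0.44, and the lineage factor Gata3 at -0.15 ± 0.38, in the authors' deposited table. The largest difference was that of Il1rl1, an IL-33 receptor gene also expressed by mast cells and basophils, at -1.58 ± 1.07 with a mean of 16.6 in the authors' deposited table, on the side of the mast cell proteases Cpa3 and Cma1 (-4.70 ± 1.98). At a minimum mean of 50, which left out Il1rl1 among the members and reduced the background to 10680 genes, the Th2 list missed the threshold (adjusted p = 0.0707) with a median of -0.18. Treg genes lay on the positive side (12 of 15, median 0.08, adjusted p = 0.0183), with a median inside the middle 95% of random lists (percentile 97.1), although Foxp3, the factor that defines Treg cells, was at -0.59 ± 0.73 with a mean of 34.9 in the authors' deposited table. Th1 genes were split 9 to 9 (adjusted p = 0.935), with Ifng at -0.21 ± 0.19 and Tbx21 at 0.05 ± 0.15 in the authors' deposited table, and Tbx21 turned to -0.02 with the trend on GC content and length removed. Naive and memory genes (adjusted p = 0.141) and T cell activation genes (adjusted p = 0.399) were not called.

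Cell cycle genes formed the group with the smallest adjusted p among the 23 lists. Of 30 tested, 29 were negative, with a median of -0.10, below all 10000 random lists (cameraPR adjusted p = 3.71e-10). Both comparisons take genes as the units, so a difference between cultures shared by these genes is left out of them. The mitotic motor genes Cenpe and Kif11 were at -0.29 ± 0.12 and -0.21 ± 0.11, the topoisomerase gene Top2a at -0.19 ± 0.09 and the proliferation marker Mki67 at -0.38 ± 0.29 in the authors' deposited table. Replication-dependent histones, made during DNA synthesis, lay the other way (14 of 17 positive, median 0.06, adjusted p = 0.00217), with Hist1h1c at 0.13 ± 0.08 in the authors' deposited table. The histone call ended with the GC and length trend removed (adjusted p = 0.664, median -0.00). The list of mitochondrially encoded mRNAs was negative in 8 of 10 (median -0.25, adjusted p = 2.78e-06), among them mt-Nd1, a complex I subunit, at -0.23 ± 0.10, and mt-Co1, a complex IV subunit, at -0.27 ± 0.21 in the authors' deposited table. Of the 10 members, 5 had an SE at least 2 times the running median at their mean, mt-Co1 among them. The members mt-Co2 and mt-Co3 had means of only 10.1 and 13.4 in the authors' deposited table. The mitochondrial ribosomal RNAs, which the list does not hold, were at 0.11 ± 0.08 (mt-Rnr2) and 0.16 ± 0.25 (mt-Rnr1) in the authors' deposited table. Nuclear long non-coding RNAs were negative in 9 of 10 (median -0.18, adjusted p = 6.71e-07), with Kcnq1ot1 at -0.30 ± 0.13 beside Malat1 in the authors' deposited table. Its fixed members also included Gas5 (0.00 ± 0.12), Snhg1 (-0.15 ± 0.17) and Snhg12 (-0.12 ± 0.22) in the authors' deposited table. Where these RNAs lie in the cell was not measured. With the GC and length trend removed the median of this list was -0.12 with 3 of 10 positive (adjusted p = 0.00133), and Kcnq1ot1 was at -0.11.

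On the positive side, ribosomal protein genes had 25 of 27 members positive (median 0.06, cameraPR adjusted p = 2.98e-07), and this call ended with the GC and length trend removed (adjusted p = 0.0786). Cholesterol synthesis genes had 18 of 20 positive (median 0.07, adjusted p = 4.75e-04), with Msmo1 at 0.19 ± 0.13 and Fdft1, squalene synthase, at 0.13 ± 0.11 in the authors' deposited table. Of the p53 targets 17 of 22 were positive (median 0.05, adjusted p = 0.00803), with the cyclin-dependent kinase inhibitor gene Cdkn1a at 0.12 ± 0.10 in the authors' deposited table. Glycolysis and hypoxia genes had 17 of 20 positive (median 0.04, percentile 91.6 of random lists, adjusted p = 0.0093), a call that also ended with the GC and length trend removed (adjusted p = 0.327). Type I interferon response genes, 18 positive and 20 negative, were not called (adjusted p = 0.487), nor were the integrated stress and unfolded protein responses (adjusted p = 0.935) or heat shock and immediate early genes (adjusted p = 0.315). Reference genes were not called (adjusted p = 0.399), with Actb at 0.07 ± 0.08 and Gapdh at 0.04 ± 0.08 in the authors' deposited table. List members given as examples beyond the named genes were chosen after their values were seen.

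**Figure D2:**
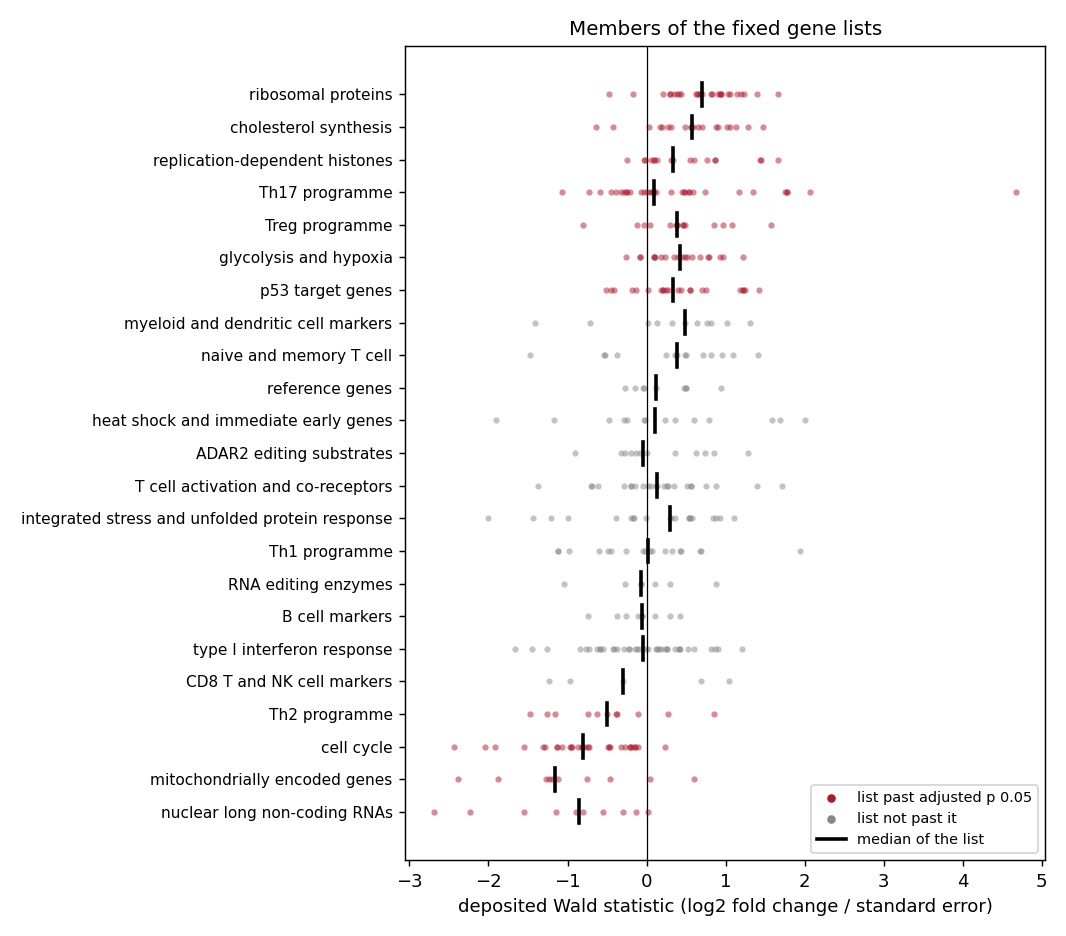
Wald statistics (fold change over standard error, no unit) in the authors' deposited table of the tested members of each gene list, 1 point per gene, with a black mark at the list's median; red marks lists with a cameraPR adjusted p below 0.05. Of the 30 cell cycle genes, 29 lie below 0, and of the 27 ribosomal protein genes, 25 lie above it.

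Markers of other cell types were present. Myeloid and dendritic cell markers were positive in 9 of 11 (median 0.43, percentile 99.98 of random lists), the side of Ccl6, although the test on Wald statistics did not call them (adjusted p = 0.182). The same test without a filter on low means did call them (16 tested, adjusted p = 0.0401), as did the test on log2 fold changes (adjusted p = 4.24e-05). The direction of the mean Wald statistic turned when only the 5 markers with a mean of at least 50 were kept (-0.0582 relative to other genes, adjusted p = 0.841). Most had low means, such as Csf1r at 1.35 ± 1.32 with a mean of 11.7 in the authors' deposited table. B cell markers (9 tested, adjusted p = 0.757) and CD8 T and NK cell markers (5 tested, adjusted p = 0.663) were not called, although the CD8 T and NK median of -0.14 lay at percentile 1.41 of random lists. Of the erythroid markers and of the sex-linked genes 1 each was tested, Alas2 at -0.32 ± 0.97 and Xist at -0.19 ± 0.09 in the authors' deposited table. Across the 23 tested lists, 0 members passed over all genes tested, and only Il17a passed adjusted over the list alone.

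The list tests above used cameraPR with a preset correlation of 0.01 on Wald statistics, and on log2 fold changes none of the 11 calls held (adjusted p from 0.0797 to 0.753). With a preset correlation of 0.1 only the cell cycle, mitochondrial and nuclear non-coding lists (each adjusted p = 0.00105) and the ribosomal proteins (adjusted p = 0.00563) remained, and the others ended: Th17 and Th2 (adjusted p = 0.119 each), Treg (0.148), cholesterol synthesis (0.059), histones (0.0876), and p53 targets and glycolysis (0.144 each). Given the SE in the authors' deposited table, a gene passing alone would have needed a log2 fold change of 0.93 at the median SE of the 10680 genes with a mean of at least 50, and 0.59 at a mean of at least 1000; genes with a smaller SE needed less.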

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

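The settings on GC content and length, scaled Wald statistics, background, Th17 members and higher correlation were chosen after the data were seen. No paired analysis was possible because the columns of values per library carry no sample labels. For the same reason DESeq2 and edgeR refits, other size factors, other pseudocounts, groups from the treatment tag, omission of a culture, fry and an estimated correlation were not run. Against 0 genes in the main result, 3 passed at an adjusted p of 0.1, and 3 and 2 passed at 0.05 when the adjustment covered genes with a mean of at least 10 or 50, since fewer genes were tested (Il17a, adjusted p = 0.0351 and 0.031). Removal of the GC and length trend over genes with a mean of at least 10 gave 3 genes. Scaling the Wald statistics by their own spread gave 7 (4 positive, 3 negative), which assumes that most genes do not differ, and both steps together 5 (3 positive, 2 negative). With the deposited adjustment, no gene passed at 0.01 or at 0.05 with a log2 fold change of at least 1. Against 11 lists, 1 was called on log2 fold changes, where noisy genes of low mean weigh as much as others, and 4 at a preset correlation of 0.1. The remaining settings called between 8 and 12. Adarb1 passed under none of the settings run. At an unadjusted p of 0.381 in the authors' deposited table, a change of adjustment alone could not have let it pass. For single genes and lists, 175 values kept direction and side of the threshold, 24 lost a call, 10 gained one and 7 changed sign without a call. Direction could not change under several settings. Adjustment over genes with a mean of at least 10 or 50 leaves a gene's fold change as it was. Ranks and the preset correlation of 0.1 leave a list's mean Wald statistic as it was. Depths per library were not used here, so the deposited standard errors set what was detectable.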

Other observations

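The tests of low counts and of mast cell and basophil markers were chosen after the results were seen, as were the comparisons of gene types and standard errors. Small nucleolar RNAs lay with Snord17 on the negative side: the median log2 fold change of 49 tested genes was -0.26 (cameraPR adjusted p = 3.86e-04, and 3.94e-04 with the GC and length trend removed). Sense intronic transcripts had a median of -0.21 over 73 genes (adjusted p = 0.013) and antisense transcripts -0.14 over 421 genes (adjusted p = 0.0245). Unconfirmed transcripts that still need experimental support, the TEC class, had a median of -0.21 over 609 genes (adjusted p = 3.86e-04). Protein-coding genes stood at 0.01 (adjusted p = 0.0376). Gene types were tested on Wald statistics at the preset correlation of 0.01 alone. The preset of 0.1 and the test on log2 fold changes, under which list calls ended, were not tried for them.

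Several immune genes had standard errors far above those of genes with a similar mean. For the B cell gene Ms4a1 the SE was 11.9 times the running median, with a log2 fold change of -0.42 ± 3.97 at a mean of 177 in the authors' deposited table. Igkc, an immunoglobulin light chain gene, stood at 7.43 times. Of the 9 tested B cell markers, 5 had an SE at least 2 times the running median, against 63 of all 10680 genes with a mean of at least 50. Some cytokine and effector genes, picked here for their high ratios, did so too: Gzmc at 6.03 times, Il17f at 5.19, Il13 at 4.67 and Il22 at 3.45. The lineage factor Gata3 stood at 3.74 times. Other cytokine and effector genes stayed below 2 times, among them Il17a, Ifng, Prf1, Il21, Csf2, Tnf, Gzmb and Il4. Among genes with a mean of at least 1000, ratios jumped from 1.34 (Havcr2) straight to 2.59 times (Rrbp1). Values per culture were not used, so a ratio below 2 does not show that a gene's cultures were alike. By list, 5 of 33 Th17, 3 of 11 Th2 and 0 of 18 Th1 genes reached 2 times the running median. Of the mitochondrially encoded genes 5 of 10 did. The platelet genes Pf4 and Ppbp were at -3.54 ± 3.15 and -3.34 ± 3.08 in the authors' deposited table.

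Cell cycle genes lay on the negative side with a median of -0.10. Fold changes followed GC content across 14547 genes (Spearman 0.24, genes not being independent replicates), with a median of -0.07 in the eighth of genes lowest in GC and 0.07 in the highest. That trend as the whole cause is argued against, since the list kept an adjusted p of 1.02e-10 and a median of -0.09 after its removal, when the ribosomal protein, histone and glycolysis calls were lost. A hypothesis of fewer dividing cells in the arm with the lower values stays open: with the trend removed, the histones made in S phase had a median of -0.000998, inside the random limits of -0.04 to 0.05, and their uncorrected median of 0.06 depends on the correction itself. An effect of the Adarb1 guide or of a guide and Cas9 cut against an empty vector may also underlie the pattern. Neither was tested, since the control carried no guide. A difference between the cultures unrelated to the guide could give the pattern as well. That was not tested either, since values per culture were not used.

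Wald statistics were narrower than a standard normal, so that 61 genes had an unadjusted p below 0.05 where about 1469 would by chance. Low counts as the whole cause are argued against, because the SD was still 0.734 among 3664 genes with a mean of at least 1000. Its 95% bootstrap interval was 0.713 to 0.753. That interval resampled genes, which share the same libraries and are not independent, so it leaves out the spread between repeat experiments. Among these 3664 genes 48, or 1.31%, had an unadjusted p below 0.05. Differences between the 2 donors left in the error term could widen every SE, but the authors' formula is not given in the sources used here and this was not tested. No biological explanation was tested.

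Cpa3 and Cma1, both mast cell proteases, lay at -5.66 ± 1.26 and -4.70 ± 1.98 in the authors' deposited table. A hypothesis is that the cultures with the higher values held a few mast cells or basophils, although the cells were started from naive CD4 T cells. Of the 11 other markers with a fold change, 9 were negative (exact binomial p = 0.0654, two-sided), among them Il1rl1, which is also in the Th2 list, so the test leaves the hypothesis open. These markers had a median mean of 1.30 normalized counts and may rest on reads of 1 library, so they are not independent, and 3 of the 16 markers listed had a mean of 0. Kit, the one with the highest mean (66.8), was at 0.03 ± 0.54 in the authors' deposited table, and a difference within the T cells was not tested.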
